A study of Mus musculus with 2 samples.

How the data were processed

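H3K4me1 was measured by ChIP-seq in hindbrain of mouse embryos at embryonic day 11.5, in 2 biological replicates that were separate pools of embryos. Per the labels, replicate 1 merged 2 technical replicates and replicate 2 had 1. Both samples form 1 group, and the replicate numbers come from the labels. The authors deposited 4 peak lists in narrowPeak format on mm10 (GRCm38): peaks of replicate 1, peaks of replicate 2, peaks of both replicates pooled, and replicated peaks, which per the deposited descriptions derive from the other 3 lists and which were checked to be a subset of the pooled peaks. The read aligner, the peak caller and its version, its threshold, the use of a control and the rule for a replicated peak are not given in the sources used here. Read counts and signal tracks were not used here.

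The value of a peak in the authors' lists is a fold, a linear ratio over control or background. The deposited p-values and q-values are on the -log10 scale. The score in the deposited lists is a rescaled number that was not used. Folds and p-values are the authors' own per-peak values, and they served to describe, rank or filter peaks within a list and to recover fragment numbers. The lists are permissive, since the lowest -log10 q was 0.271 in replicate 1, 0.247 in replicate 2 and 0.0496 in the pooled list, so many weak peaks are included. The shares of peaks with a -log10 q of 2 or more were 26.6% in replicate 1, 42.4% in replicate 2, 30.2% in the pooled list and 39.6% in the replicated list.

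The number of fragments behind each peak was recovered from the authors' fold and p-value, as the whole number whose Poisson tail gives the p-value within 0.001 on the -log10 scale, with the background that the fold implies when 1 is added to both. This held for 100% of the peaks in the replicate lists and, with coverage scaled by 0.627, in the pooled list. With no scale 1.10% of the pooled peaks met the tolerance by chance, and 4.96% of the peaks of replicate 1 did after p-values were shuffled. The lowest background per base put the depth of replicate 1 at 1.04 times that of replicate 2. Small fragment numbers (medians of 9, 10 and 19) limit the precision of each peak's presence and fold.

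Peaks were compared by overlap of at least 1 bp, with shares given with Wilson 95% intervals (for the replicated share in place of the exact intervals first planned) and set against 100 shifts of one list along the chromosomes. Genes were the protein-coding genes of GENCODE vM21, which is on the same assembly, with the 5' end of the gene as its TSS. This is the farthest 5' end of any transcript of the gene, also for Hoxa3, Hoxc5, Hoxd3 and Hoxd4, whose records extend into neighbouring genes. Each base was assigned to promoter (within 1 kb of a TSS), exon, intron or intergenic sequence in that order. A gene's value was the percentage of the window of 25 kb either side of its TSS that peaks covered. Neighbouring genes share parts of their windows. For the Hox genes a window of 2.5 kb either side was used too. Sequence was taken from the reference FASTA of GRCm38.

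There was no second group, so no test between conditions was made. The error is the spread between the replicates' own lists, each cut by p-value to 75542 peaks, the length of the shorter list, and is given as an SD with n = 2. It leaves out the difference in length between the full lists (135087 and 75542 peaks), so it may understate the variation between replicates. It describes those lists and is no error of a value from the replicated list, which is another peak set. The 25 gene lists, the motifs, the alternatives and the rule for named genes were fixed before the data were examined. The lists, written from textbook knowledge, cover hindbrain patterning, hindbrain neuron types, neural progenitors, pan-neuronal genes, forebrain factors, Hox groups 1 to 5 and 9 to 13, 6 signalling pathways (Sonic hedgehog, Wnt, Notch, retinoic acid, FGF and BMP), cell cycle, housekeeping, vascular endothelium, mesenchyme, neural crest, erythroid cells, microglia, heart, liver, skeletal muscle, limb and chemosensory receptors. The symbol Ahsp of the erythroid list had no match in the annotation. A list's median was placed among 10000 random lists (1000 for the receptors) of the same size matched on the number of protein-coding TSSs in the window. The percentile describes this tissue and is no p-value, and a list was called above or below outside the central 95%. On simulated data, 3.6% of 1000 unchanged lists of 25 genes were called above and 0 below, and 23.7% of lists with coverage raised 2-fold and 48.5% of lists with coverage raised 3-fold were called above. Fragment recovery was exact for 100% of 19951 simulated peaks with no coverage scale and for 99.995% of 19577 with a scale of 0.6. A planted RFX motif was found in simulated sequence, and 2 of 27 motifs and reversed motifs that were not planted had an interval that left out 1.

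Genes were named by this rule: up to 4 highest and 3 lowest members of each list, the 20 genes of highest coverage with windows that do not overlap, the nearest TSS of the 10 peaks of highest fold, the Hox genes, and the 5 genes with the largest difference between replicates in each direction. The text gives part of the genes so selected. Consensus matches of 14 motifs were counted on both strands in peaks over 2 kb from any annotated transcript start and in flanks of equal width 5 kb away that overlap no peak in any list. The ratio of matches per kb has an exact 95% interval for counting error. For flanks matched on GC, which were drawn with replacement, this interval is too narrow. Motifs were also reversed without complementing, as a control of base composition. Reversal does not keep dinucleotides. It brings a CG into the RFX, NFI and CTCF sequences and, where the variable base is C, into the E-box, and removes that of ETS. For these motifs the control is not neutral.

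Alternatives were a -log10 q of 2 or more, a fold of 3 or more, each replicate's list alone, overlap of 50% of the peak or reciprocal, equal list lengths, other windows or gene bodies, 2-kb promoters, every transcript start in place of the gene's 5' end, no matching of random lists, and flanks 10 kb away or matched on GC. GC-matched random lists, GC-matched bins for the X chromosome, promoter classes by CpG content (CpG ratio of 0.6 and GC content of 50% or more within 500 bp), all pooled peaks, and peaks that overlap both replicates' lists were added after the data were examined. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.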

Results

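H3K4me1, monomethylation of lysine 4 on histone H3, is a chromatin mark found at enhancers and around promoters. It was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in hindbrain dissected from mouse embryos of the strain B6NCrl at embryonic day 11.5, when the hindbrain holds dividing progenitors and newly born neurons. There was 1 group with 2 biological replicates, and each replicate was a separate pool of embryos of both sexes, 109 embryos for replicate 1 and 88 for replicate 2. No second tissue, stage or condition was part of the series, so the comparisons are between the replicates, between parts of the genome and between gene groups within this tissue. The authors' peak lists held 135087 peaks for replicate 1, 75542 for replicate 2, 55818 for both replicates pooled and 40579 replicated peaks, all of them peaks of the pooled list. The replicated peaks had a median width of 291 bp and covered 14.6 Mb, 0.552% of the mm10 genome. The median peak rested on 9 fragments at its summit in replicate 1, 10 in replicate 2 and 19 in the pooled list, as recovered from the authors' fold and p-value of each peak.

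Most H3K4me1 peaks of either replicate were weak, and how many the other replicate shared rose with the number of fragments behind them. Of the peaks of replicate 1, 30.4% (Wilson 95% interval 30.2 to 30.7%) overlapped a peak of replicate 2 by at least 1 bp, and 53.2% (52.9 to 53.6%) of the peaks of replicate 2 overlapped a peak of replicate 1. Lists shifted along the chromosomes overlapped by 1.60% and 2.83% on average over 100 shifts. Peaks of replicate 1 with 7 or fewer fragments were shared in 13.9% of cases and those with 20 or more in 92.8%, and the corresponding shares for replicate 2 were 34.6% and 94.9%. Cut to the same number of peaks, the lists shared 39.3% and 40.5%. These intervals cover counting error only. Among the 33051 replicated peaks that overlapped both lists, the fold of the peak in replicate 1 and in replicate 2 correlated weakly across peaks (Pearson r = 0.249, Spearman rho = 0.204), and peaks are not independent replicates.

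**Figure D1:**
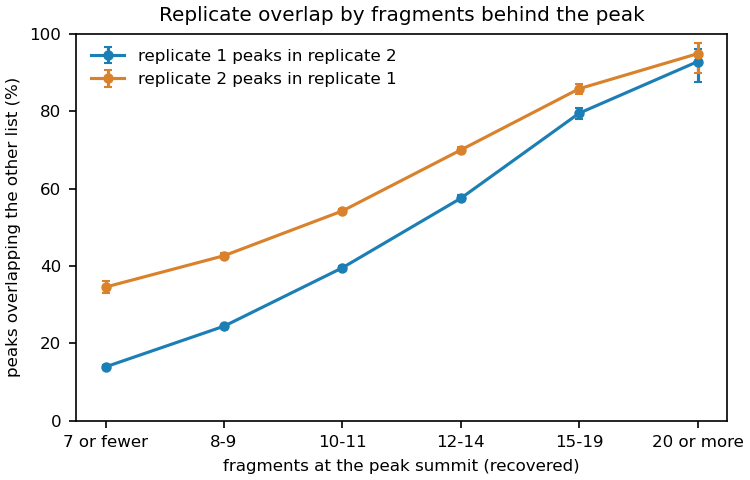
Share of each replicate's peaks that overlap a peak of the other replicate (vertical axis, %), by the number of fragments recovered at the peak summit (horizontal axis). Bars are Wilson 95% intervals. The share rises from 13.9% to 92.8% for replicate 1 and from 34.6% to 94.9% for replicate 2, whose highest classes hold 153 and 136 peaks.

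The replicated list held 72.7% (72.3 to 73.1%) of the pooled peaks. Ranked by fold and divided into 5 classes of equal size, the weakest pooled peaks were kept in 45.7% of cases and the strongest in 97.0%. Of the replicated peaks, 95% overlapped a peak of replicate 1 and 86.3% a peak of replicate 2. Replicated peaks were used for all gene-level values that follow, and each value is followed by the SD between the replicates' own lists cut to 75542 peaks each (n = 2), unless stated otherwise. Because those lists held more peaks, the replicates' own coverage was in most cases higher than that by replicated peaks. The SD is therefore no error of the value it follows, which can lie outside both replicates by many SDs. The SD leaves out the difference in length between the replicates' full lists.

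H3K4me1 peaks lay mainly inside genes and away from their 5' ends. Introns held 51.5% of the bases of replicated peaks (51.1 ± 0.0077% in the replicates' own lists, SD, n = 2), intergenic sequence 26.8% (29.6 ± 0.0072%), promoters within 1 kb of the 5' end of a protein-coding gene 12.7% (11.2 ± 0.149%) and exons 8.96% (8.09 ± 0.149%). Relative to the share of the genome in each class, promoters held 8.15 times their share (7.18 ± 0.0954 in the replicates, SD, n = 2), exons 2.75 times, introns 1.47 times and intergenic sequence 0.446 times. The median distance from a replicated peak to the nearest protein-coding transcription start site (TSS) was 18.7 kb, and 13.4% of the peaks lay within 1 kb of a TSS.

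Peaks covered the sequence downstream of the TSS more often than the TSS itself. Of 21911 protein-coding TSSs, 3.42% (3.19 to 3.67%) were covered by a replicated peak, against 8.34% (7.98 to 8.72%) of the positions 1000 bp downstream and 3.69% (3.45 to 3.95%) of those 500 bp upstream, where the interval overlapped that at the TSS. In the replicates' own lists the upstream maximum lay above the TSS with separate intervals, at 5.46% (5.17 to 5.77%) against 4.53% (4.26 to 4.81%) in replicate 1 and at 5.09% (4.81 to 5.39%) against 4.30% (4.04 to 4.58%) in replicate 2. The downstream maximum was 2.44 times the value at the TSS, and 2.19 ± 0.180 times in the replicates (SD, n = 2). Promoters were also divided by sequence, after the data were examined. At the 9727 CpG-rich promoters coverage rose from 2.89% (2.57 to 3.24%) at the TSS to 6.49% (6.01 to 6.99%) at 900 bp upstream and 14.4% at 1100 bp downstream. At the 12184 CpG-poor promoters it was 3.85% (3.52 to 4.21%) at the TSS and at most 4.11% (3.77 to 4.48%) downstream, with overlapping intervals.

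**Figure D2:**
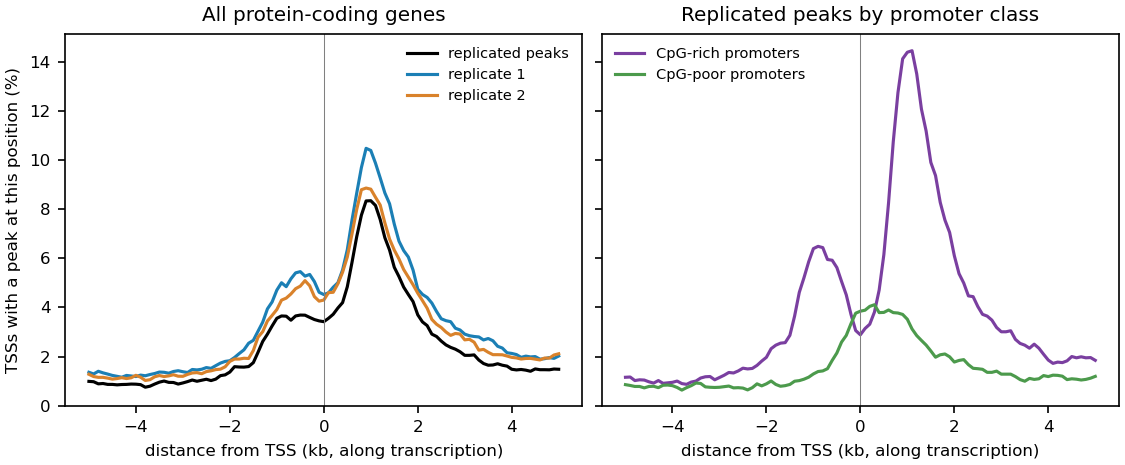
Share of protein-coding TSSs with a peak (vertical axis, %) at each distance from the TSS (horizontal axis, kb, positive along transcription). Left, replicated peaks and both replicates' own lists at equal peak number; right, replicated peaks at CpG-rich and CpG-poor promoters, where the CpG-rich class reaches 14.4% downstream and the CpG-poor class 4.11%.

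Genes that pattern the hindbrain and define its progenitor domains were densely marked. All 29 genes of this list had a replicated peak within 25 kb of the TSS, and the median member had 3.70% of its 50-kb window covered (SD 0.487). This median lay above all 10000 random lists matched on the number of neighbouring TSSs. Pax7, a dorsal neural tube transcription factor, had 15.5% of its window covered (SD 3.75; TSS at chromosome 4, 139833528), Wnt1, the secreted signal of the midbrain-hindbrain boundary and roof plate, 14.1% (SD 2.67; chromosome 15, 98789857), Gbx2, a homeodomain factor of the anterior hindbrain, 13.1% (SD 3.74; chromosome 1, 89931179) and Neurog1, a proneural factor, 10.8% (SD 2.55; chromosome 13, 56252163). The least covered members were Pax8 at 0.34%, Pbx3 at 0.49% and Olig3 at 0.94%. Across all 21911 protein-coding genes the median was 0.364%, and 51.9% of the genes had a replicated peak in the window.

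Factors of hindbrain neuron types were marked likewise, with a peak near 30 of 31 genes and a median of 2.93% (SD 0.222). Lmx1b, which is required for serotonergic neurons, led with 13.1% (SD 1.60), followed by Barhl1 at 7.57% (SD 0.59), the motor neuron factor Lhx3 at 7.05% (SD 2.90) and Gata2 at 6.59% (SD 1.66). The lowest members were Tph2, the tryptophan hydroxylase of serotonin synthesis, with no replicated peak in its window, Dbh, which makes noradrenaline, with 0.41% and the glutamate transporter gene Slc17a6 with 0.53%. The neural progenitor list had a median of 4.67% (SD 0.746), with a peak near 20 of 24 genes. Notch1 had 24.4% of its window covered (SD 1.85), Nes, the intermediate filament of neural stem cells, 20.4% (SD 2.58), and the RNA-binding proteins Msi1 and Msi2 15.8% and 15.1% (SD 2.33 and 2.75). Prom1, Ptprz1 and Slc1a3 had none. Of the pan-neuronal genes, 18 of 26 had a peak and the median was 2.21% (SD 0.568). Ebf3 (14.2%, SD 2.44), Celf3 (6.95%), Nhlh1 (6.65%) and Elavl3 (6.28%) led, while Elavl2, Elavl4 and the X-linked gene Dcx had no replicated peak. The 3 medians lay above all 10000 random lists.

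Genes of 6 signalling pathways active in the neural tube also lay above all their random lists. The list medians were 4.14% for Notch (SD 0.383), 4.10% for retinoic acid (SD 0.149), 3.76% for FGF (SD 0.0933), 3.19% for Wnt (SD 0.446), 3.09% for BMP (SD 0.017) and 3.08% for Sonic hedgehog (SD 0.107). In the Notch list, 16 of 18 genes had a peak, and after Notch1 the most covered were Hes5, a Notch target, at 13.2% (SD 1.99), the ligand Dll1 at 11.96% (SD 0.48) and Lfng, a glycosyltransferase acting on Notch, at 11.9% (SD 0.70). Rbpj, the DNA-binding partner of Notch, and Hey2 had none. In the retinoic acid list, the receptor genes Rara (25.8%, SD 4.71; chromosome 11, 98927818) and Rxra (15.3%, SD 2.11), the retinol uptake receptor Stra6 (17.0%, SD 2.24) and the binding protein Crabp2 (13.9%, SD 2.23) led, and Rarb, Aldh1a1 and Nrip1 had no replicated peak. All 20 Wnt genes had a peak, with Axin2, a feedback target of the pathway, at 9.99% (SD 2.18) and Wnt7b at 7.73% (SD 3.02). Fgfr3 at 13.1% (SD 3.31) and Fgfr2 at 9.3% (SD 3.11) led the FGF genes, Smad7 at 21.9% (SD 1.05) and Id3 at 13.2% (SD 2.78) the BMP genes. Of the Sonic hedgehog genes, the coreceptor Boc (13.9%, SD 0.82), the receptor Ptch1 (9.79%, SD 1.66) and Shh itself (5.21%, SD 1.43) led, and Smo and Foxa2 had none.

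Lists chosen for other regions and cell types were partly marked as densely, so the measure did not separate hindbrain genes from all others. The forebrain list had a median of 3.17% (SD 0.462), led by the neighbours Dlx1 and Dlx2, both at 5.49%, and by Foxd1 at 4.60%, and the limb list had 3.21% (SD 0.370), led by Lmx1b, which the neuron list also holds, and by Sp6 at 7.5% and Msx1 at 7.14%. Forebrain, with a peak near 23 of 25 genes, and limb, with 16 of 18, lay above all 10000 random lists. Housekeeping genes (2.37%, SD 0.174), with Gapdh at 9.25% and Rplp0 at 5.51%, lay at percentile 99.95. Skeletal muscle (2.43%, SD 0.0658) lay at percentile 99.98, and Pax7, which the hindbrain list shares, was its most covered member, with the troponin Tnnt3 at 9.70% and desmin (Des) at 8.31% next and Myf5, Myf6 and Myh3 at 0. Mesenchyme (1.42%, SD 0.160; Foxf1 5.97%, Foxc2 4.72%) lay at 99.89, neural crest and cranial ganglia (1.502%, SD 0.0594; Ngfr 7.84%, Ntrk1 7.43%) at 99.86, and vascular endothelium (1.45%, SD 0.154; Eng 4.93%, Sox18 3.82%) at 99.45. With random lists matched on the GC content of the window too, skeletal muscle fell to percentile 81.8 and endothelium, which was at 96.0 with the list of replicate 1 alone, to 84.3, inside the central 95% of random lists, and 15 lists stayed above instead of 17. Coverage was related to GC content across genes (Spearman rho = 0.699), and genes are not independent replicates.

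The remaining lists did not rise above their random lists. Cell cycle genes had a median of 1.08% (SD 0.350; Cdk4 8.07%, Ccnd1 7.65%) at percentile 97.2, microglia and macrophage genes 1.58% (SD 1.475; C1qb 4.73%, Fcer1g 4.68%) at 96.8, and heart genes 0.671% (SD 0.0445; Myl7 4.36%, Hand2 4.01%) at 89.2. With the list of replicate 1 alone cell cycle rose to 98.0 and microglia to 99.7, both above the random lists. Liver genes, with a peak near 8 of 18, and erythroid genes, with 7 of 17, both had a median of 0 and lay at percentiles 19.3 and 12.1, and the erythroid list fell to 2.29, below the random lists, with the list of replicate 1 alone. The liver genes Alb, Afp and Apoa1, the red cell gene Epb42 and the X-linked red cell genes Gata1 and Alas2 had no replicated peak in their windows. Of the 1479 chemosensory receptor genes, 24 had a peak, and their median of 0 lay below all 1000 random lists, whose median was 0.428%. That call ended with GC-matched random lists, whose median was also 0, and with a -log10 q of 2 or more, a fold of 3 or more, peaks that overlap both replicates' lists, 10-kb windows, gene bodies and unmatched random lists. In simulations none of 1000 unchanged lists of 25 genes was called below, since medians of 0 are common in lists of that size.

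**Figure D3:**
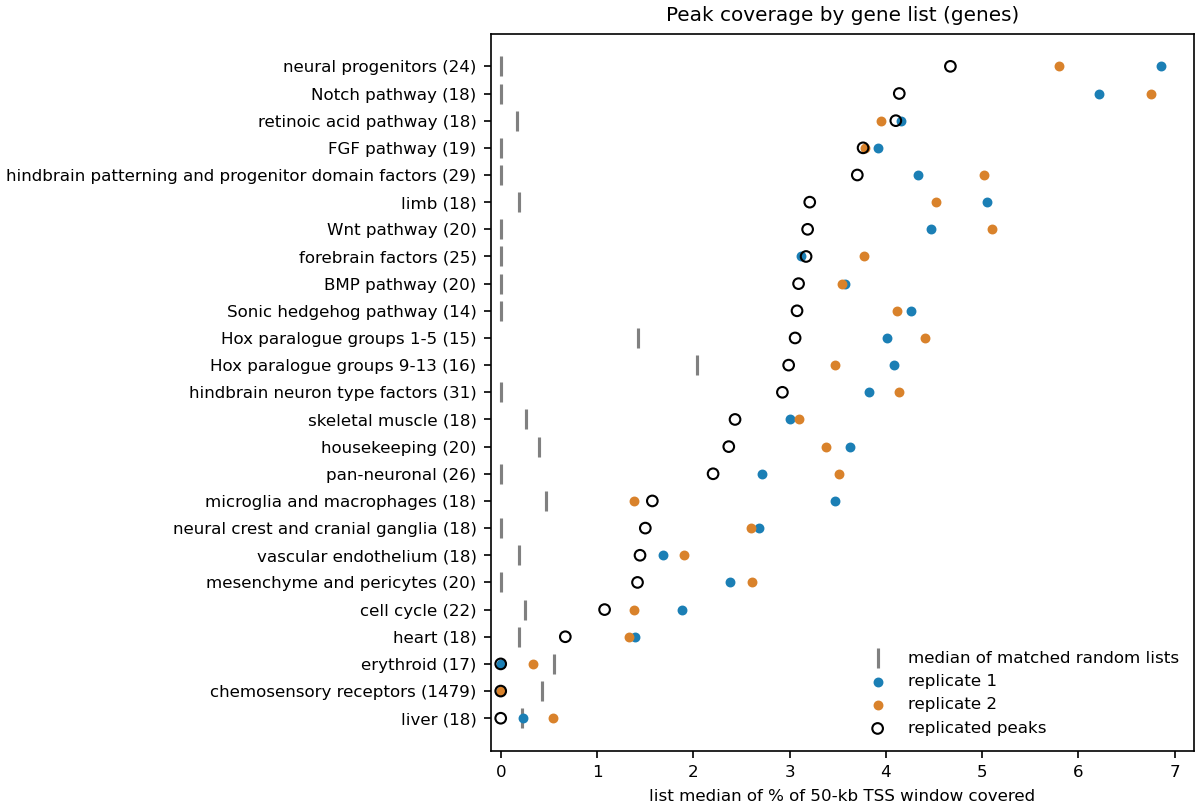
Median over each gene list of the share of the 50-kb TSS window covered by peaks (horizontal axis, %), with the number of genes in parentheses. Open circles are replicated peaks, filled circles each replicate's own list at equal peak number, and grey ticks the median of matched random lists; with replicated peaks neural progenitors have a median of 4.67%, and liver, erythroid and chemosensory receptor genes have 0.

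The Hox clusters, whose genes set segment identity along the hindbrain and spinal cord, carried scattered small peaks. Replicated peaks covered 4.42% of the length of the Hoxd cluster (3.63% and 6.32% in replicates 1 and 2), 3.80% of Hoxa (6.46% and 4.54%), 1.71% of Hoxb (2.99% and 2.81%) and 1.17% of Hoxc (1.76% and 2.74%), and the order of Hoxa and Hoxd differed between the replicates. In the 5 kb around the TSS, paralogue groups 1 to 5, which hindbrain segments express, had a mean of 3.48% (SD 0.281), groups 6 to 8 had 6.39% (SD 0.273) and groups 9 to 13, the posterior genes, had 4.38% (SD 0.525). The difference between groups 1 to 5 and 9 to 13 was -0.895 percentage points with replicated peaks, 1.11 in replicate 1 and -0.028 in replicate 2, with an SD of 0.805 between replicates and opposite signs in them, so no direction was established. With replicated peaks, Hoxb1, a gene of rhombomere 4, had the highest coverage of its TSS window, though in neither replicate alone, at 19.8% (14.4% and 14.1% in the replicates; chromosome 11, 96365752 to 96368256), followed by Hoxb9 at 18.9% (22.4% and 13.8%), Hoxd1 at 15.9% (11.04% and 16.5%) and Hoxa13 at 14.9% (23.4% and 7.2%). Hoxa2, Hoxa9, Hoxa10, Hoxb3, Hoxb13, Hoxc11, Hoxd3 and Hoxd4 had no peak in this window in the replicated list or in either replicate's list at equal peak number. Outside this window, replicated peaks covered 2.74% of the gene body of Hoxa10, 1.71% of that of Hoxb3 and 0.86% of that of Hoxd3. The TSSs used for Hoxd3 and Hoxd4 nearly coincide (chromosome 2, 74711927 and 74711929), so both rest on the same window. That of Hoxc5 (chromosome 15, 102967443) lies beside that of Hoxc10 (102966796), so groups 1 to 5 and 9 to 13 share sequence there. Over the 50-kb windows, the lists of groups 1 to 5 (median 3.06%, SD 0.279) and 9 to 13 (2.99%, SD 0.435) lay at percentiles 94.4 and 81.6 of random lists, which were drawn from genes with equally many neighbours. Groups 1 to 5 rose above them, to 98.3, with the list of replicate 2 alone. Hox genes lie together and share much of their windows, while the random lists hold genes from the whole genome. These percentiles are thus not calibrated for the Hox lists, and no call rests on them.

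**Figure D4:**
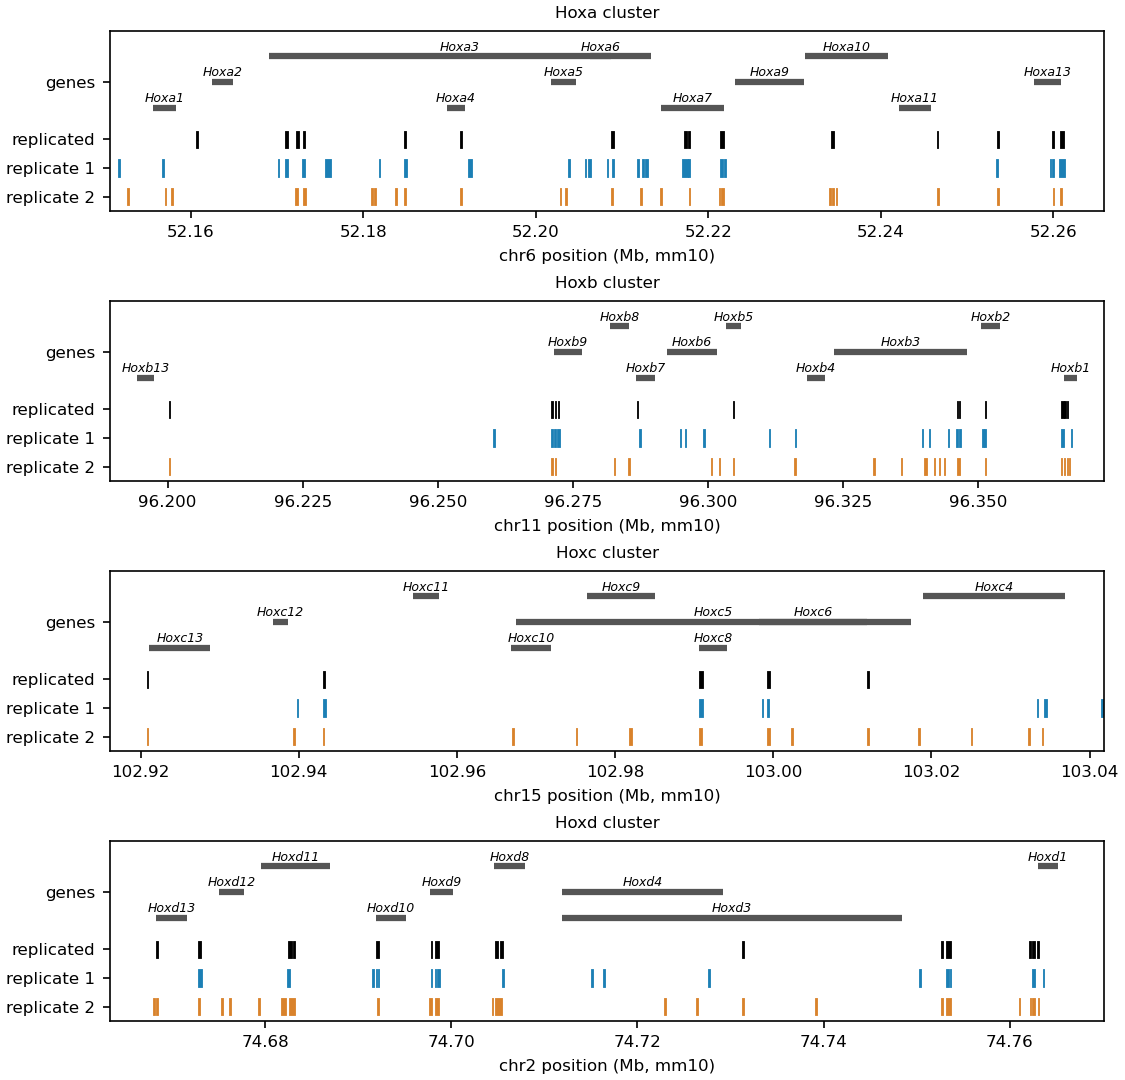
Map of the 4 Hox clusters with mm10 positions (Mb) on the horizontal axis. Grey bars are genes, and vertical marks are replicated peaks (black) and peaks of replicate 1 (blue) and replicate 2 (orange) at equal peak number, drawn at their width; the replicated peaks cover 4.42% of Hoxd and 1.17% of Hoxc.

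Among the 50-kb windows, replicated peaks covered that of Cxxc5 most, which codes for a CXXC zinc finger protein. The gene had 36.6% of its window covered (SD 1.04; TSS at chromosome 18, 35829397) by 27 peaks. Bahcc1 followed with 34.2% (SD 0.03; chromosome 11, 120232947), then Tle3, a Groucho-family corepressor, with 31.7% (SD 4.78; chromosome 9, 61372366), Fignl2 with 30.2% (SD 1.3) and Fam222a with 27.8% (SD 0.40). Rara, the nuclear receptor corepressor Ncor2 (25.5%, SD 3.65), Zmynd8 (25.04%, SD 0.05), Notch1, the actin-binding protein drebrin (Dbn1, 23.5%, SD 1.26), Smad7, Bcl9l, a Wnt pathway coactivator (21.7%, SD 0.92), and Celsr2, a planar cell polarity cadherin (21.1%, SD 3.35), were also among the 20 highest. For Bahcc1 (31.52% and 31.47%) and Zmynd8 (22.97% and 22.9%) both replicates lay below the value by replicated peaks, so these small SDs do not bound it. For Tle3 the replicates lay on both sides, at 34.85% and 28.08%. Of the 20 genes, 15 were among the 20 highest of replicate 1 and 15 among those of replicate 2. Windows of 10 kb and 50 kb either side of the TSS kept 8 and 9 of them.

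The strongest replicated peak by the authors' fold, 8.88 over background and 46 fragments, lay in an intron of Tmem94, 14818 bp downstream of its TSS (chromosome 11, 115779314 to 115780479). The next lay in an intron of Gse1, 91367 bp downstream of the nearest TSS, that of Gins2 (chromosome 8, 120497031 to 120499401; fold 7.95), in an intergenic region 155507 bp upstream of Gm26897 (chromosome 5, 111578211 to 111579433; fold 7.90) and, each at a fold of 7.76, in introns of Cpne5, Prrc2b and Spsb4 and an exon of Cstad. A peak 4860 bp upstream of Prox1, a homeodomain gene of neuronal differentiation, had a fold of 7.57 (chromosome 1, 190175146 to 190175729), as had peaks 22627 bp downstream of the TSS of Ccr7 and in an intron of Mdga1. These folds are the authors' values from the pooled list and have no replicate error.

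Coverage differed between chromosomes, and the X chromosome was almost free of peaks. Chromosome 11 was covered over 1.27% of its sequence (SD 0.0827), the most of any chromosome, and chromosome 3 over 0.319% (SD 0.0473), the least of any autosome. The X chromosome held 56 of the replicated peaks, or 0.342 per Mb against 16.9 per Mb on the autosomes, and its coverage of 0.0092% was 1.502% of the autosomal value (3.22 ± 0.338% in the replicates, SD, n = 2). Against autosomal 100-kb bins matched on GC content and TSS number, a comparison chosen after the data were examined, the X was at 7.06% (bootstrap 95% interval 3.71 to 11.5%). In the replicates' own lists it was at 11.9 ± 0.302% of matched bins (SD, n = 2), above that interval. No replicated peak lay on the Y chromosome.

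**Figure D5:**
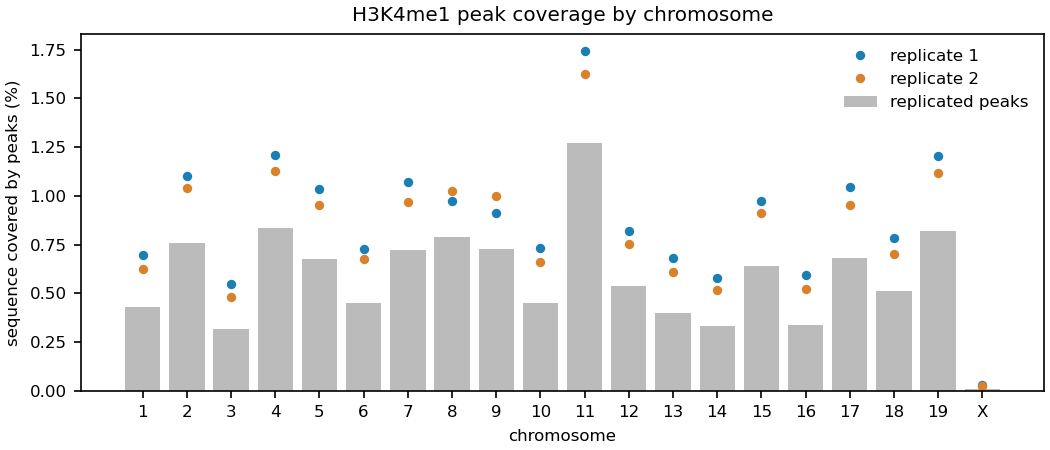
Share of each chromosome's sequence covered by peaks (vertical axis, %). Bars are replicated peaks and points each replicate's own list at equal peak number; chromosome 11 is highest at 1.27% and the X chromosome is at 0.0092%.

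Of 14 binding motifs of transcription factor families, RFX, NFI, E-box, SOX, MEIS, nuclear receptor and TEAD motifs were more frequent in distal peaks than in the flanking sequence. The 23890 distal peaks, over 2 kb from any TSS, were compared with flanks 5 kb away, and each motif with its reversed sequence. The RFX motif had the largest ratio of matches per kb, 4.59 (exact 95% interval 3.41 to 6.28; 3.98 ± 0.0569 in the replicates, SD, n = 2), from 211 matches in peaks and 56 in flanks. The E-box of the proneural factors had a ratio of 1.44 (1.41 to 1.47; 1.45 ± 0.0043), SOX 1.36 (1.2996 to 1.421; 1.28 ± 0.0086), MEIS 1.34 (1.3022 to 1.3831; 1.35 ± 0.029), the nuclear receptor motif 1.15 (1.11 to 1.19; 1.16 ± 0.0097) and TEAD 1.13 (1.09 to 1.17; 1.12 ± 0.0047). For the E-box, SOX, MEIS, nuclear receptor and TEAD motifs the interval also lay above that of the reversed motif, whose ratio was 0.610 for the E-box and 1.10 for SOX and for MEIS. With the list of replicate 2 alone this no longer held for TEAD. The reversed E-box can hold a CG that the motif lacks, and it stayed low with flanks matched on GC, at 0.684. For the E-box the comparison with the reversed motif therefore adds little to the ratio itself. NFI had a ratio of 2.06 (1.60 to 2.68). The RFX interval lay above that of its reversed control too (0 to 2.95), except with the list of replicate 2 alone. That control had only 0 matches in peaks and 3 in flanks and holds a CG that the motif lacks, so it cannot show enrichment beyond composition. The reversed control of NFI, with 3 and 1, had too few matches to compare. CTCF (0.936), ETS (1.19), MEF2 (0.843) and HNF1 (0.406) had intervals that included 1. With flanks matched on GC, CTCF fell to 0.493 (0.357 to 0.676) and MEF2 rose to 1.94 (1.38 to 2.74). Those flanks were drawn with replacement, so some matches count repeatedly and the intervals are too narrow. CTCF had 117 matches in them against 82 in the whole set they came from, so its fall rests partly on repeated flanks. ETS rose to 1.53 (1.13 to 2.09) with flanks 10 kb away and to 1.48 (1.18 to 1.86) with the list of replicate 2 alone. Reversed ETS was at 1.32 in both settings and reversed MEF2 at 1.19 with GC-matched flanks, with intervals that overlapped those of the motifs. With the list of replicate 2 alone, MEF2, at 0.818 (0.675 to 0.989), and HNF1, at 0.255 (0.0476 to 0.890), lay below 1. The AT-rich homeodomain (0.711), PBX-HOX (0.725) and GATA (0.779) motifs lay below 1. Peaks had a GC content of 52.6% and flanks of 46.0%, and with flanks matched on GC the homeodomain and PBX-HOX ratios turned to 1.62 and 1.49 and that of GATA, at 0.971 (0.881 to 1.07), was no longer below 1. With those flanks the PBX-HOX interval (1.3248 to 1.6749) lay only just above that of its reversed control (1.13, 0.9705 to 1.3152). Because these intervals are too narrow, that separation was not established. Homeodomain did not exceed its reversed control (1.57), and the nuclear receptor ratio fell to 1.01 (0.977 to 1.05). The E-box (1.19, 1.16 to 1.22), MEIS (1.18), NFI (1.45, 1.13 to 1.87) and TEAD (1.06, 1.02 to 1.10) fell too but stayed above 1. RFX (4.83) and SOX (1.40) did not fall.

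The replicates' coverage of gene windows was compared at equal peak number. Across the 21911 genes the coverage of replicate 1 and replicate 2 had a Pearson r of 0.931 and a Spearman rho of 0.864, a correlation across genes that are not independent replicates. The difference had a median of 0 and an SD of 1.08 percentage points, against a median coverage of 0.766% in replicate 1 and 0.680% in replicate 2. The largest excess of replicate 1 was at Cirbp, a cold-inducible RNA-binding protein, with 29.5% against 20.1% of the window, followed by Gipc3 (20.8% against 12.9%), Cracr2b, Tnfrsf25 and Tle3. The largest excess of replicate 2 was at the cadherin gene Cdh22, with 18.5% against 10.9%, followed by the kinase gene Jak3 (10.2% against 3.59%), Igsf9b, Dusp3 and AC124108.1. Jak3 lies on chromosome 8 and Igsf9b on chromosome 9, the only autosomes covered less in replicate 1 than in replicate 2. Chromosome 8 was covered over 0.9745% against 1.0249% and chromosome 9 over 0.914% against 1.0017%. In proportion these chromosome differences were far smaller than those at Jak3 and at Igsf9b (4.09% against 10.46%). A shift of the whole chromosome thus leaves most of the excess at both genes unaccounted for, and Tle3, also on chromosome 9, went the other way. With 1 value per replicate these differences could not be tested.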

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

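Alternatives chosen only after the data were examined were GC-matched random lists, matched bins for the X chromosome, promoter classes, all pooled peaks and peaks that overlap both replicates' lists. The share of replicate 1 peaks in replicate 2, 30.4%, became 20.7% with an overlap of 50% of the peak, 14.3% with a reciprocal overlap of 50%, 34.0% with a -log10 q of 2 or more, 32.2% with a fold of 3 or more and 39.3% at equal list lengths. The share of replicate 2 peaks in replicate 1, 53.2%, became 39.2%, 25.6%, 38.7%, 46.7% and 40.5% under the same settings. The replicated share of pooled peaks rose from 72.7% to 95.2% with a -log10 q of 2 or more and to 80.9% with a fold of 3 or more. The promoter fold of 8.15 became 7.76 with a -log10 q of 2 or more, 8.28 with a fold of 3 or more, 7.41 with a 2-kb promoter and 7.11 to 7.24 without either replicate. The ratio of the downstream maximum to the TSS, 2.44, became 2.68 with a -log10 q of 2 or more, 2.06 to 2.31 without either replicate, 5.0 at CpG-rich and 1.07 at CpG-poor promoters. The Hox difference of -0.895 became -0.028 to 1.11 without either replicate. Windows of 10 and 50 kb kept 8 and 9 of the 20 highest genes. The X chromosome's coverage, 1.502% of the autosomal one, became 0.654% with a -log10 q of 2 or more, 2.08% with all pooled peaks, 7.06% against matched bins and 2.98 to 3.46% without either replicate. The value against matched bins became 3.76% with a -log10 q of 2 or more and 11.7 to 12.1% without either replicate. The X coverage stayed far below 100% in each. The number of gene lists above random lists, 17, ranged from 15 to 20 over the alternatives. The number below, 1, became 0 with a -log10 q of 2 or more, a fold of 3 or more, peaks that overlap both replicates' lists, 10-kb windows, gene bodies, unmatched and GC-matched lists, and 1 to 2 without either replicate. Chemosensory receptors moved from percentile 0 to 50 with a -log10 q of 2 or more, 10-kb windows, gene bodies and GC matching, where the list and the random lists had a median of 0, and to 7.2 with a fold of 3 or more, 18.9 with peaks that overlap both replicates' lists and 2.70 unmatched. Vascular endothelium moved from 99.45 to 96.0 with 10-kb windows, 94.8 with 50-kb windows, 79.5 with gene bodies, 84.3 with GC matching, and skeletal muscle from 99.98 to 81.8 with GC matching. Without matching on neighbouring TSSs, Hox groups 1 to 5 rose to 99.97, groups 9 to 13 to 99.95 and microglia to 98.7, and cell cycle rose to 98.9 with a fold of 3 or more. Without either replicate the percentiles ranged from 93.1 to 98.3 for Hox groups 1 to 5, from 94.5 to 98.0 for cell cycle, from 2.29 to 7.60 for erythroid, from 81.8 to 99.7 for microglia and from 96.0 to 99.04 for vascular endothelium. The percentiles of the Hox lists, whose genes share much of their windows, are not calibrated under any of these settings. The lists of hindbrain patterning, hindbrain neuron types, neural progenitors, pan-neuronal genes, forebrain, limb, mesenchyme, neural crest, housekeeping and the 6 signalling pathways stayed above under each of these alternatives of peak set, window or matching. The homeodomain, PBX-HOX and MEF2 ratios turned from 0.711, 0.725 and 0.843 to 1.62, 1.49 and 1.94 with flanks matched on GC, and CTCF fell from 0.936 to 0.493. With those flanks the E-box fell from 1.44 to 1.19, MEIS from 1.34 to 1.18 and NFI from 2.06 to 1.45. The nuclear receptor motif fell from 1.15 to 1.01 and TEAD from 1.13 to 1.06. GC-matched flanks were drawn with replacement, so the fall of CTCF rests partly on repeated flanks. The cause of these changes was not tested, except that fewer peaks or another GC content enter by construction. Of the values of named genes under alternative peak sets, 658 moved by at most 1 SD between replicates and 457 by more. Peaks with few fragments were shared least between the replicates, and the median peak of replicate 1 rests on 9 fragments. Whether depth limits the weak peaks most was not tested. No paired analysis was possible because there is 1 group.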

Other observations

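Part of the distal peaks lay in dense clusters. This grouping, the tests of the muscle, endothelium and limb lists against GC content, both tests of the pooled list and the comparison of X and autosomes by number of peaks were chosen after the data were examined. Joined where neighbours lay close to each other, the 23890 distal peaks formed 10186 clusters, of which 5805 held a single peak and 266 held 10 or more. The cluster with the most covered sequence lay over Gse1 (chromosome 8, 120251836 to 120567684), where 191 peaks covered 33.2% of 315.8 kb (SD 0.184 between the replicates' lists, n = 2). The covered share counts distal replicated peaks only. The SD is between the replicates' lists with all their peaks in the span, which covered 36.079% and 35.819% there, so it is no error of that share. The next lay over Msi2, an RNA-binding protein of neural progenitors, with 122 peaks over 23.8% of 235.5 kb (SD 2.14; chromosome 11, 88394505 to 88629970). Clusters over the axon guidance genes Ephb2 (68 peaks, 26.015%, SD 0.957) and Slit1 (51 peaks, 21.5%, SD 0.926), over Ssbp3 (60 peaks, 22.9%, SD 2.23), Nav2 (58 peaks, 15.5%, SD 0.793) and Ncor2 (42 peaks, 29.3%, SD 2.25), and over Notch1 (34 peaks, 30.3%, SD 1.05) were among the 15 with the most covered sequence.

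The X chromosome was almost free of peaks in the replicated list and held few in the replicates' full lists (765 in replicate 1 and 190 in replicate 2). Autosomal bins matched on GC content and TSS number raised the X coverage from 1.502% to 7.064% of theirs (bootstrap 95% interval 3.71 to 11.5%). With the lists of replicates 1 and 2 at equal peak number it was at 12.1% and 11.7% of matched bins. These features thus account for part of the gap and not for the whole. With 50% of its fragments, as for a single marked copy, 12.44% of the autosomal pooled peaks would still pass the lowest p-value of the list, so a lower number of marked X copies in embryos of both sexes could account for part of the rest. By number of peaks in the same list, the X held 10.7% (bootstrap 95% interval 6.43 to 15.9%) of the peaks of matched bins, an interval that includes 12.44%. In the full lists of replicate 1 and replicate 2, 35.5% and 22.5% would pass, above the 24.4% (19.6 to 30.3%) and 13.2% (9.60 to 17.5%) that the X held. The passing shares are of all autosomal peaks and not of those in matched bins, and fragments were cut without sampling noise. These values therefore do not decide whether part of the gap would be left. With 75% of the fragments 87.4% of the pooled peaks would pass. Other biological explanations were not tested.

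The skeletal muscle and endothelium lists lay above random lists although the tissue was hindbrain. With random lists matched on GC content their percentiles fell to 81.78 and 84.26, because the random medians rose from 0.262% to 1.76% and from 0.185% to 0.960% while the lists' own medians of 2.43% and 1.45% stayed, so the GC content of their windows may account for both calls. The limb list stayed above, at 99.32, which argues against GC content as the whole cause. Without the 11 of its 18 members that other lists also hold, its percentile among GC-matched lists was 82.86 and its median 2.96% instead of 3.21%, and with 7 genes left the loss of the call cannot be told apart from that of a smaller list. No biological explanation was tested.

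The pooled list was shorter than either replicate's list although it joins both. Merging of neighbouring peaks as the whole cause is argued against by the covered sequence, since the pooled list covered 87.55% of the bases that the list of replicate 2 covered. It may still account for part, since the median pooled peak was wider, at 250 bp against 198 bp in replicate 1 and 220 bp in replicate 2. The folds and p-values of the pooled peaks fitted coverage that was scaled down before the pooled call. This is inferred under the Poisson model used to recover fragments, since the sources used here do not state it. The background predicted from both replicates and the recovered scale of 0.627 was 1.00 times the one found in the pooled list, so that the pooled list had 1.23 and 1.28 times the depth of replicates 1 and 2 and not the sum of both. Because the depth stayed above that of either replicate, these values do not decide whether the scaling shortened the list, and no biological explanation was tested.

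A hypothesis was that peaks with an RFX motif lie near genes of cilia, which RFX factors regulate. Of 286 such peaks, 1 lay within 25 kb of the TSS of a cilium gene, against 127 of 40292 other peaks (odds ratio 1.11, 95% interval 0.0278 to 6.35, Fisher's exact two-sided p = 0.596). Another was that peaks with a PBX-HOX motif lie near hindbrain patterning genes. Of 993 such peaks 7 did, against 201 of 39585 others (odds ratio 1.391, 0.551 to 2.93, Fisher's exact two-sided p = 0.363). Both intervals are too wide to exclude an enrichment of 1.5-fold or none.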
